A study of Penicillium citrinum with 6 samples.

How the data were processed

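The series holds RNA sequencing of wild-type *Penicillium citrinum* mycelium in 6 libraries, 2 each of CK2D, TL2D and TL3D. The titles do not spell these codes out. They were matched to the growth description through the sampling days, since plates were sampled at day 2 and leaves at days 2 and 3. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples.

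Per the file headers, the deposited tables give FPKM for each replicate (fragments scaled by gene length and by all fragments of the library, made by the authors). They cover 9385 genes. Cufflinks is named in the submitters' processing notes, with no version. The aligner, genome build and annotation are not given in the sources used here. The deposited fold change column is a ratio, the mean FPKM of one group over that of the other, and the deposited log2 column is its log2. Recomputed folds matched 100% of genes within 0.001 on the log2 scale, with a mean of 0 set to 0.0001 as the authors did. The authors' deposited FDR is a p-value adjusted for multiple tests, and the tool and test behind it are not given in the sources used here. Genes are marked significant there when the FDR is under 0.05 and the absolute log2 change above 1. The TL2D columns were checked to be identical in both tables. Read totals are unknown, so no depth per library, counting interval or limit for a value of 0 can be given.

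Values were analysed as deposited, in R 4.3.3 with limma 3.58.1. Genes with at least 1 FPKM in at least 2 of the 4 libraries of a comparison were tested on log2(FPKM + 1), with limma's eBayes with a trend, on 2 residual degrees of freedom. p-values were adjusted by Benjamini and Hochberg's method over all tested genes of each comparison, and a gene was called at an adjusted p under 0.05. No count-based test was run, because FPKM are not counts. TL2D was compared with CK2D, TL3D with TL2D, and the changes with each other by counting genes called in both. Those counts were set against the overlap of independent lists, and their covariance against 20 simulated data sets with no change between groups.

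Before the data were examined, 33 gene lists were fixed as search terms on product names, along with the tests, the alternatives and a rule for the genes to name. The lists cover pectin, cellulose and beta-glucan, hemicellulose, starch and sucrose, and cutin and lipid breakdown; phenolic and lignin-type oxidases; peptidases; sugar, amino acid and peptide, and multidrug and ABC transport; nitrate assimilation; cytochrome P450; secondary metabolite synthases; the citrinin cluster; detoxification; nicotine and pyridine metabolism; oxidative stress defence; heat shock proteins; cytosolic ribosomal proteins; ribosome biogenesis; the TCA cycle; the respiratory chain; glycolysis; fatty acid oxidation; conidiation; the cell cycle; the fungal cell wall; plant-type names; iron and siderophores; effector-type proteins; the proteasome and autophagy; amino acid biosynthesis; and transcription factors. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists. Counts adjusted over the list alone use the p-values of that list's members only.

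The rule named, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among genes above the median expression, with no overlap between groups and an informative product name. It added the called member with the largest rise and fall of each list, every tested nitrate and citrinin gene, and the 3 conidiation genes with the highest expression. This gave 90 genes for leaves against plates and 70 for day 3 against day 2, and the rule's genes that appear in no sentence are in the counts only.

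The procedure was tested on simulated data with 50 genes changed at each size. For log2 changes of 1, 2, 3 and 4 it recovered 66%, 86%, 92% and 90% in the libraries of TL2D and CK2D, and 48%, 84%, 88% and 92% in those of TL3D and TL2D. It called 0.09% and 0.04% of unchanged genes. The simulated noise was independent between genes and had the same SD in both groups. The TL2D replicates differed more than those of the other groups, so these rates may not hold for the real libraries.

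Alternatives were each replicate left out in turn (with the tested genes kept as in the full fit), the replicate number as a block, a pseudocount of 0.1, no filter on low values, upper-quartile and median log ratio scaling, a fit over all 6 libraries, the authors' FDR, a 2-fold limit, and a stricter adjusted p of 0.01. Lists were also tested by camera with an estimated correlation and by fry. Camera with an estimated correlation works on only the 2 residual degrees of freedom, so hardly any list could pass it here. The comparison of TL3D with CK2D, its lists and its split by CK2D replicate were added after the data were seen. With 2 replicates per group, no sample was tested as an outlier and no other splits of the samples were counted.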

Results

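The series measured total RNA of *Penicillium citrinum* mycelium by RNA sequencing, in 6 libraries that fall into 3 groups of 2. CK2D is mycelium from Czapek-Dox plates, a defined medium of sucrose and nitrate, taken 2 days after conidia were spread. TL2D and TL3D are mycelium from tobacco leaves inoculated with conidia and taken after 2 and 3 days at 25 °C. Each library has an FPKM value (fragments scaled by gene length and by all fragments of the library) for 9385 genes. Gene numbers and product names are those of the tables, and 1655 genes carry the name hypothetical protein. Genome positions were not used here, because 0 of the gene numbers match the 11657 genes of the RefSeq table. FPKM per library summed to between 582600 and 614206. The number of reads behind them is unknown, so no counting interval is given. Between 7906 and 8217 genes per library reached 1 FPKM, and between 101 and 175 were listed at 0. The 10 most abundant genes held 12.6% and 12.6% of the FPKM total in the CK2D replicates, 7.3% and 6.9% in TL2D, and 11.5% and 12.3% in TL3D. Across genes, which are not independent replicates, log2 values of replicates 1 and 2 correlated at 0.996 in CK2D, 0.982 in TL2D and 0.996 in TL3D. Of 8407 genes compared, 18 lay at least 2-fold apart between the CK2D replicates, 360 between the TL2D replicates and 10 between the TL3D replicates. Below, levels are mean FPKM ± SD (n = 2 libraries per group), changes are log2 ± SE from the fit, and folds are ratios of mean FPKM. Largest rises and falls are ranked by the fitted change on log2(FPKM + 1), not by the fold. With a group mean under 1 FPKM the fold is near the floor and much larger than the fitted change. A gene is said to have risen or fallen at an adjusted p under 0.05 in limma.

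The comparison of TL2D with CK2D asks which genes differ between mycelium on leaves and on plates at the same age. On leaves the largest fitted rise among the named genes was in the pectin lyase gene PCI_6944, whose product cleaves the pectin of plant cell walls. It went from 1.33 ± 0.685 FPKM on plates to 1256 ± 187 on leaves, 945-fold (1490-fold without CK2D replicate 2; log2 9.10 ± 0.24, adjusted p = 0.000167). The endopolygalacturonase gene PCI_6081, another pectin-splitting enzyme, rose from 2.19 ± 0.434 to 500.0 ± 133 FPKM, and the fungal cellulose binding domain gene PCI_7585 from 4.05 ± 0.461 to 1212 ± 22.2. Genes for making the pigments and toxins sorbicillinoids and citrinin were among those that fell furthest. The transporter gene sorT (PCI_3053) went from 3306 ± 212 to 1.5 ± 0.115 FPKM (log2 −10.37 ± 0.10, adjusted p = 5.8e-05), and the citrinin polyketide synthase gene PCI_3406 from 197 ± 0.886 to 0.0667 ± 0.0378 (log2 −7.54 ± 0.11, adjusted p = 8.08e-05).

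Among genes above the median expression with an informative name, the naming rule picked 7 more rises. The hydrophobin gene PCI_9301, for a small protein that coats fungal surfaces, rose 163-fold (log2 6.79 ± 0.17), the polygalacturonase gene PCI_2378 rose 113-fold (6.58 ± 0.14), and the L-amino-acid oxidase gene PCI_8349 rose 104-fold (6.50 ± 0.36; 162-fold without CK2D replicate 2). The endo-beta-1,4-glucanase gene PCI_3154 rose 104-fold, the xyloglucan-specific endoglucanase gene PCI_0448 rose 82.3-fold, and the gene PCI_1876, annotated as the sterol enzyme eburicol 14-alpha-demethylase, rose 96.1-fold. The peroxidase gene PCI_2009, annotated stcC, rose 24.4-fold. Among the falls, 3 more came from the sorbicillinoid cluster, sorD (PCI_3051, log2 −8.70 ± 0.15), sorA (PCI_3054, −6.44 ± 0.11) and sorB (PCI_3055, −6.39 ± 0.14). Another 3 have citrinin-type names, mpl6 (PCI_3400, −8.82 ± 0.14), mpl1 (PCI_3405, −6.45 ± 0.11) and mpl2 (PCI_3404, −6.26 ± 0.12). The remaining 3 were a thaumatin-like protein gene (PCI_9158, −8.95 ± 0.12), a COBW domain gene (PCI_2196, −5.64 ± 0.22) and the hemophore gene cfmB (PCI_2843, −5.52 ± 0.18). Adjusted p over these 20 genes ran from 5.8e-05 to 0.001.

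**Figure D1:**
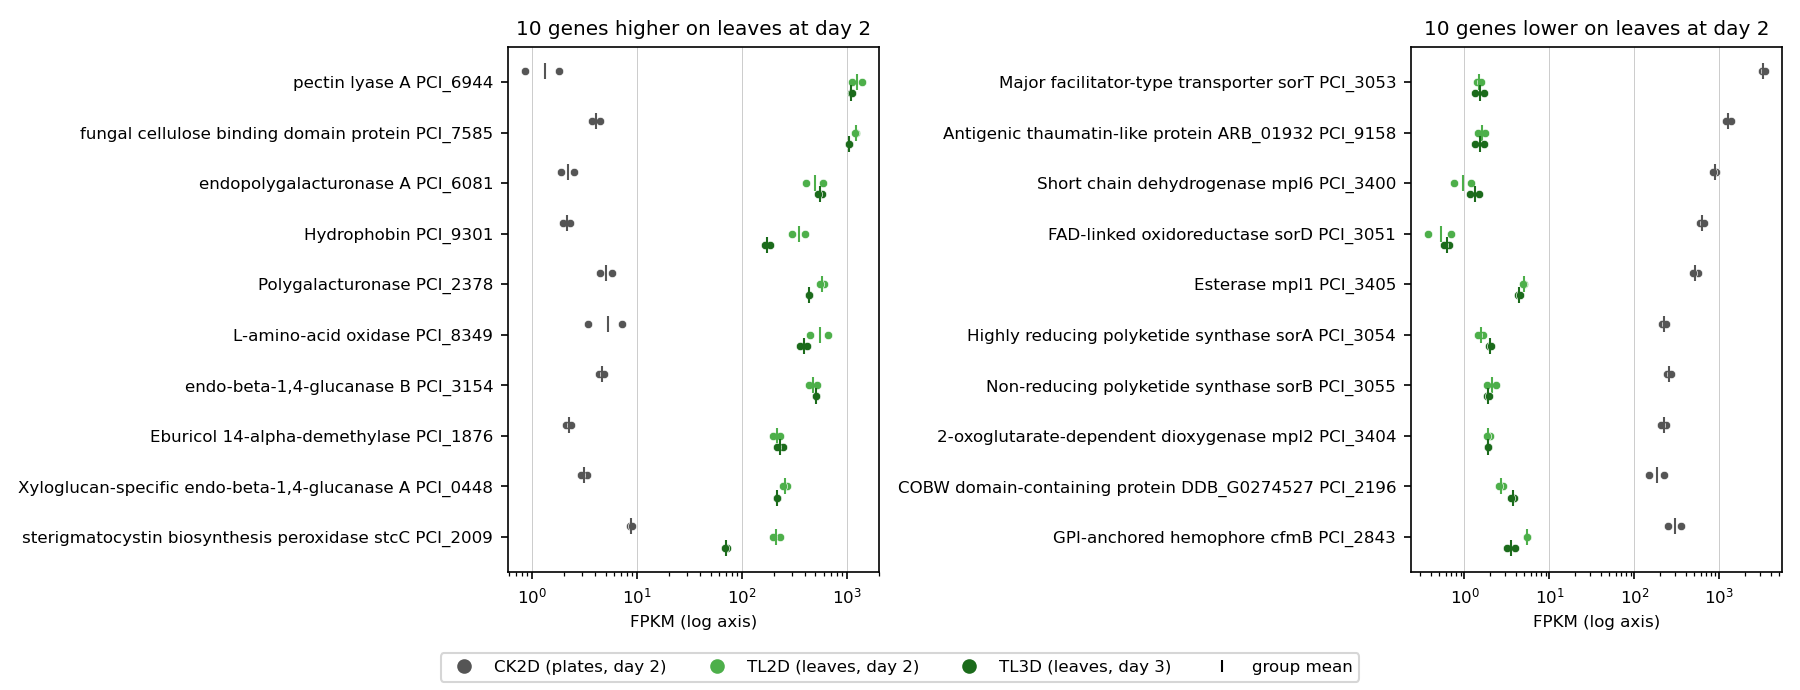
FPKM (log axis) of the 10 genes that rose most and the 10 that fell most on leaves at day 2 under the naming rule, with each point a library and each vertical tick a group mean. Pectin lyase PCI_6944 had a mean of 1.33 on plates and 1256 on leaves at day 2, and sorT had 3306 and 1.5.

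In all, 4493 of 8286 tested genes passed (54.2%), 2054 higher and 2439 lower on leaves, and 832 and 1012 of them changed at least 2-fold. The median log2 change over all tested genes was −0.099. Which direction held more genes depended on the processing, with 2327 higher and 2153 lower after median log ratio scaling and 2625 and 2385 by the authors' deposited FDR. Unadjusted, 5118 genes had p under 0.05. The values of the groups did not overlap in 82.3% of tested genes, against 33.3% by chance for 2 libraries against 2. The authors' own table marks 2339 genes as significant, 1075 higher and 1264 lower, and these include 1817 of the 1844 genes that changed at least 2-fold here.

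Of 20 tested genes of pectin degradation, 12 rose and 3 fell (13 and 3 adjusted over the list alone). The median log2 change was 1.78, and the list passed camera's test against all other genes (adjusted p = 0.0031, but adjusted p = 0.846 with an estimated correlation). Here and below, the value with an estimated correlation rests on 2 residual degrees of freedom. It cannot decide whether correlation among genes accounts for a list's call. The member that fell furthest was exopolygalacturonase C (PCI_2491), from 4.23 ± 0.431 to 1.01 ± 0.0915 FPKM. Enzymes for other plant polymers moved both ways. In the cellulose and beta-glucan list 14 of 35 rose and 11 fell (14 and 12 adjusted over the list alone). The endoglucanase PCI_3154 had the largest fitted rise, and beta-glucosidase L (PCI_0427) fell from 92.4 ± 2.23 to 2.84 ± 0.637 FPKM. That list also holds glucan 1,3-beta-glucosidases, which act on fungal wall glucan, and its median of 0.09 turned to −0.07 after upper-quartile scaling. In the hemicellulose list 12 of 45 rose and 17 fell (12 and 18 adjusted over the list alone), with endo-1,4-beta-xylanase A (PCI_7049) going from 0.0771 ± 0.0924 to 185 ± 1.87 FPKM and the arabinofuranosidase axhA (PCI_8847) falling from 10.7 ± 1.01 to 1.32 ± 0.904. In the starch and sucrose list 4 of 14 rose and 6 fell (4 and 6 adjusted over the list alone), with invertase 4 (PCI_7398) up 19.2-fold and an alpha-glucosidase (PCI_8883) down 5.61-fold. In the cutin and lipid hydrolysis list 15 of 59 rose and 21 fell (16 and 23 adjusted over the list alone). Cutinase 1 (PCI_0177), which splits the leaf's waxy cutin, was up 137-fold from 0.293 FPKM (log2 4.94), and phospholipase D (PCI_2213) was down 26.7-fold. These 4 lists did not pass camera's test (adjusted p = 0.505, 0.911, 0.594 and 0.796).

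Of 55 sugar transport genes, 8 rose and 32 fell (8 and 34 adjusted over the list alone), with a median of −0.84 (camera adjusted p = 0.00446, adjusted p = 0.846 with an estimated correlation). The high-affinity glucose transporter PCI_2887 fell from 220 ± 14.0 to 21.5 ± 4.29 FPKM, and the sugar transporter PCI_4488, annotated STL1, rose from 0.601 ± 0.384 to 4.98 ± 3.36. Of the 8 that rose, 4 are quinate permeases (PCI_3476, PCI_0093, PCI_5044 and PCI_9466), for a plant acid and not a sugar, and the members that fell include the regulator RGT1 (PCI_9078). Of 27 secondary metabolite synthase genes, 4 rose and 16 fell (6 and 18 adjusted over the list alone), with a median of −0.81 (camera adjusted p = 0.0315, adjusted p = 0.846 with an estimated correlation). The synthetase PCI_8142, annotated FUB8, rose most in that list, from 0.163 ± 0.0445 to 4.67 ± 1.5 FPKM. In the citrinin list 1 of 6 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.264). The list was matched by name and is not the whole cluster. It leaves out mpl1, mpl2, mpl4, mpl6 and mpl7 of the consecutive numbers PCI_3398 to PCI_3407, and holds PCI_4327, PCI_5674 and PCI_5755 from elsewhere. All 10 genes of PCI_3398 to PCI_3407 fell at least 2-fold (median log2 −7.14). Besides the synthase, the transporter mrr1 (PCI_3407) went from 86.5 ± 10.6 to 0.296 ± 0.0115 FPKM and the activator mrl3 (PCI_3403) from 55.0 ± 2.86 to 14.8 ± 3.00. A second gene annotated mrr1 (PCI_4327) rose from 15.5 ± 0.216 to 62.5 ± 12.4. The activator ctnR (PCI_5674) stood at 1.59 ± 0.144 and 1.44 ± 0.117, and ctnC (PCI_5755) at 2.20 ± 0.272 and 2.09 ± 1.97, neither past the test (adjusted p = 0.658 and 0.736). Without TL2D replicate 1, ctnC gave a log2 change of −0.91 (adjusted p = 0.0123), and without TL2D replicate 2 it gave 0.49 (adjusted p = 0.0753). The nitrate list split, with 3 of 5 up and 2 down, the same adjusted over the list alone (camera adjusted p = 0.467). The nitrate transporter PCI_3791 had 14.5 ± 0.439 FPKM on plates and 74.1 and 30.3 in the leaf replicates. The nitrite reductase PCI_3792 rose 3.72-fold and the nitrate reductase PCI_3793 rose 3.17-fold. A further nitrate reductase (PCI_1262) fell 4.75-fold (8.45-fold without TL2D replicate 1). The copper-containing nitrite reductase PCI_1263, a denitrification enzyme, fell 6.75-fold (109-fold without TL2D replicate 1), from 3.92 ± 0.105 FPKM to 1.13 and 0.0359 in the leaf replicates, and had no call with a pseudocount of 0.1 or by the authors' FDR (adjusted p = 0.0605 and 0.172).

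Of 54 ribosome biogenesis genes 53 rose and 0 fell (53 and 0 adjusted over the list alone), with a median of 1.36 (camera adjusted p = 2.31e-18, adjusted p = 0.846 with an estimated correlation). Nucleolar protein 16 (PCI_5227) rose 4.02-fold. Of 73 genes in the cytosolic ribosomal protein list 70 rose and 1 fell (70 and 1 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 2.51e-16, adjusted p = 0.846 with an estimated correlation). The member that rose most was loc1 (PCI_7024), an assembly and export factor and no ribosomal protein itself, and the L30 gene PCI_4575 fell 2.06-fold. Of 32 TCA cycle genes 20 rose and 3 fell (20 and 3 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.000238, adjusted p = 0.846 with an estimated correlation). Both extremes of that list, PCI_0484 up 9.32-fold and PCI_1758 down 5.18-fold, are succinyl-CoA:3-ketoacid transferases, which use ketone bodies. The rises also hold lysine synthesis genes (PCI_8932, PCI_4524 and PCI_4213) and leucine synthesis genes (PCI_0104 and PCI_0346), matched by name alone. Of 58 respiratory chain and ATP synthase genes 31 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 3.95e-07, adjusted p = 0.846 with an estimated correlation, fry adjusted p = 0.0519). An alternative oxidase (PCI_9062), which bypasses part of the chain, rose 4.78-fold. Of 46 amino acid biosynthesis genes 23 rose and 7 fell, the same adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0101, adjusted p = 0.846 with an estimated correlation). Methionine synthase PCI_5779 rose 4.66-fold, and a tryptophan synthase (PCI_6632) fell 4.56-fold (7.43-fold without TL2D replicate 1). The falls include an S-adenosylmethionine synthase (PCI_3430) and a homoserine lactonase (PCI_1800), which make no amino acid.

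Of 32 iron and siderophore genes 15 rose and 7 fell, the same adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.0283, adjusted p = 0.846 with an estimated correlation, fry adjusted p = 0.0593). The siderochrome transporter PCI_4951, which takes up iron chelates, rose 27.5-fold, and the ferric reductase component PCI_5211 fell 8.83-fold. Without TL2D replicate 1 this list's median was 0.23 (adjusted p = 0.104). Of 142 proteasome and autophagy genes 8 rose and 50 fell (6 and 43 adjusted over the list alone), with a median of −0.24 (camera adjusted p = 0.00398, adjusted p = 0.846 with an estimated correlation, fry adjusted p = 0.0692). After median log ratio scaling 9 of these genes rose and 34 fell, with a median of −0.15. The autophagy gene PCI_5616 fell 4.15-fold, and PCI_9139, annotated creD and tied to carbon repression, rose 2.10-fold. Of 232 transcription factor genes 32 rose and 90 fell (30 and 90 adjusted over the list alone), with a median of −0.33 (camera adjusted p = 0.0369, adjusted p = 0.846 with an estimated correlation, fry adjusted p = 0.0801). Camera's adjusted p for transcription factors was 0.0671 without CK2D replicate 2, 0.052 without TL2D replicate 1, 0.104 without TL2D replicate 2, and 0.0584 with the replicate number as a block. A C2H2 factor (PCI_9458) rose 11.6-fold, and a factor of the sorbicillinoid cluster (PCI_3052) fell 31.4-fold.

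**Figure D2:**
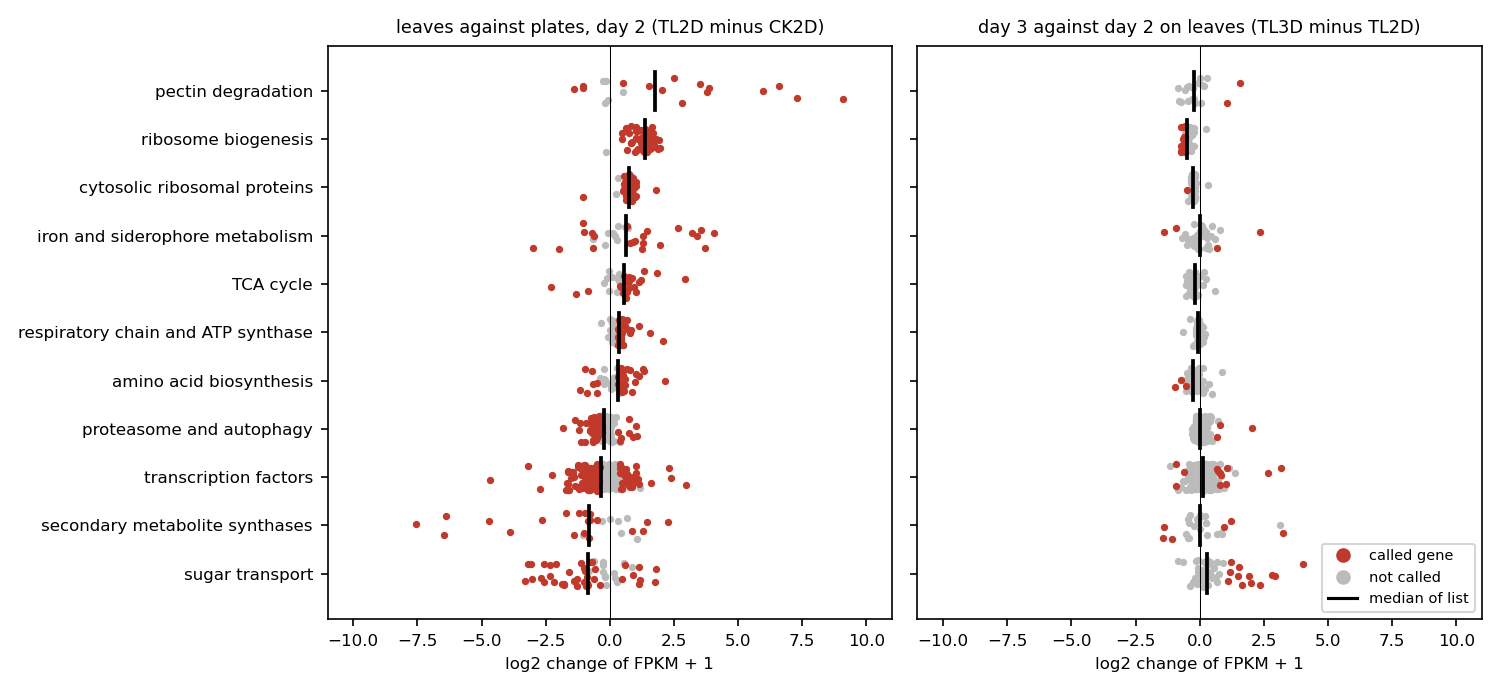
Log2 change of each tested member of the 11 lists that passed camera's test on leaves against plates, for TL2D minus CK2D and for TL3D minus TL2D, each point a gene, red if called and grey if not, with black ticks for list medians. The ribosome biogenesis list has a median of 1.36 in the comparison with plates and −0.51 between day 2 and day 3 on leaves.

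The remaining lists did not pass camera's test, with adjusted p from 0.242 to 0.964. In conidiation and conidia 3 of 14 rose and 7 fell (3 and 8 adjusted over the list alone). The hydrophobin PCI_0227, among the most abundant transcripts on plates, fell from 16661 ± 669 to 4925 ± 1641 FPKM, while the hydrophobin PCI_2115 rose from 359 ± 63.5 to 1919 ± 307. The hydrophobin PCI_2310 stood at 2089.7 ± 79.0 and 1176 ± 536 (adjusted p = 0.0784). The conidiophore regulator abaA (PCI_1856) fell 4.99-fold (7.68-fold without TL2D replicate 1). In oxidative stress defence 12 of 37 rose and 8 fell (13 and 9 adjusted over the list alone), with a catalase (PCI_2755) up 19.0-fold and a superoxide dismutase (PCI_1659) down 25.4-fold (39.8-fold without TL2D replicate 2). In multidrug and ABC transport 35 of 87 rose and 27 fell (37 and 30 adjusted over the list alone). ABC transporter C (PCI_2853) was up 329-fold from 0.283 FPKM (log2 6.16), and the sulfite pump SSU1 (PCI_0658) was down 22.2-fold. In cytochrome P450 17 of 52 rose and 18 fell (19 and 19 adjusted over the list alone), with gsfF (PCI_8438) up 73.0-fold and yanH (PCI_1024) down 18.0-fold. In phenolic and lignin-type oxidases 11 of 30 rose and 13 fell, the same adjusted over the list alone. Its largest rise, 203-fold from 0.272 FPKM in PCI_2499 (log2 5.42), is a catechol O-methyltransferase and no oxidase. The chloroperoxidase PCI_3553 went from 165 ± 0.229 FPKM to 27.5 and 0.86 in the leaf replicates (adjusted p = 0.057 with a pseudocount of 0.1, 0.0507 with no filter on low values and 0.0782 by the authors' FDR).

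In peptidases 23 of 116 rose and 43 fell, the same adjusted over the list alone, with a dipeptidase (PCI_1286) up 8.59-fold and aspergillopepsin-2 (PCI_4066), a secreted acid protease, down 11.6-fold. In amino acid and peptide transport 13 of 51 rose and 4 fell (10 and 2 adjusted over the list alone), and PCI_8661 rose 6.28-fold while PCI_9424 fell 3.52-fold. In detoxification 6 of 37 rose and 12 fell, the same adjusted over the list alone, with the reductase yakc (PCI_7554) up 11.9-fold and the transferase FUS3 (PCI_2118) down 3.90-fold. In nicotine and pyridine metabolism 5 of 21 rose and 2 fell, the same adjusted over the list alone, but 7 rose and 0 fell after median log ratio scaling. Its extremes are a pyrroline-5-carboxylate reductase (PCI_7274), a proline enzyme, up 3.48-fold, and a pyrrolopyrazine cluster gene (PCI_0231), down 1.37-fold (adjusted p = 0.0218, and 0.0547 after that scaling). In heat shock proteins 17 of 52 rose and 13 fell (19 and 13 adjusted over the list alone), with cns1 (PCI_0345) up 3.07-fold and hsp9 (PCI_1781) down from 423 ± 41.2 FPKM to 21.2 and 99.5 in the leaf replicates. In glycolysis 7 of 21 rose and 3 fell, the same adjusted over the list alone, with hexokinase-1 (PCI_6407) down 4.80-fold and a glyceraldehyde-3-phosphate dehydrogenase (PCI_5166) up 3.38-fold (5.08-fold without CK2D replicate 2). In fatty acid oxidation and glyoxylate cycle 10 of 67 rose and 22 fell (9 and 15 adjusted over the list alone). Malate synthase (PCI_7166), a glyoxylate enzyme, fell 2.01-fold. A carnitine monooxygenase subunit (PCI_9392) rose 473-fold (155-fold without TL2D replicate 1) from 0.0769 FPKM on plates to leaf values of 36.3 ± 34.6 (log2 4.71).

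In cell cycle and DNA replication 11 of 88 rose and 22 fell, the same adjusted over the list alone, with a division GTP-binding gene (PCI_0742) up 2.16-fold and PHO85 cyclin-1 (PCI_0447) down 2.65-fold. In fungal cell wall genes 11 of 37 rose and 9 fell (12 and 10 adjusted over the list alone), with phiA (PCI_6057) up 4.23-fold and a class III chitinase (PCI_7897) down 5.69-fold (9.33-fold without TL2D replicate 1). In secreted effector-type genes 3 of 11 rose and 3 fell, the same adjusted over the list alone, with a LysM gene (PCI_2595) up 24.7-fold (44.8-fold without CK2D replicate 2) and a CFEM gene (PCI_4577) down 5.96-fold. Of 5 fungal gene models with plant-type names 1 rose and 4 fell, the same adjusted over the list alone, from PCI_2106 (1.85-fold up) to PCI_7450 (down from 10.8 ± 1.63 FPKM to 4.35 and 1.38 in the leaf replicates). These names come from homology, so the list is a weak measure of tobacco RNA. Median, mean and camera's direction differed in sign for hemicellulose (−0.19, 0.32, down), cutin and lipids (−0.23, 0.09, down), phenolic oxidases (−0.27, −0.34, up) and heat shock (0.05, −0.08, up). They also differed for fatty acid oxidation (−0.17, 0.11, down) and effectors (−0.11, −0.13, up), and oxidative stress had a median of 0.00, a mean of −0.19 and the direction up.

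With 2 libraries per group an exact permutation test cannot go below p = 0.333, so the calls rest on limma's pooled spread. After rounding, leaving out 1 library moved the fold more than 1.5 times in 19 of the 90 named genes, at most 16.5 times (PCI_3553). PCI_5166, at 1.5 after rounding, lay just past that limit before it and is not among the 19. The count falls to 1134 without CK2D replicate 1 and 1131 without CK2D replicate 2, and 23 and 22 of the 90 named genes then lose their call, among them PCI_1262, PCI_1263, PCI_3791, PCI_0227 and PCI_1856 in both cases, while all 4493 genes kept their direction, with median absolute log2 changes of 0.87 and 0.86 against 0.86.

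The comparison of TL3D with TL2D asks how the mycelium on leaves changes from day 2 to day 3. The catalase A gene PCI_9497, for an enzyme that removes hydrogen peroxide, rose from 0.792 ± 0.628 to 37.1 ± 6.58 FPKM (log2 4.44 ± 0.29, adjusted p = 0.0112). The transcription factor gene atf21 (PCI_1410) rose from 18.2 ± 2.17 to 173 ± 48.7, and the glucose-repressible gene PCI_1153 from 142 ± 27.9 to 1216 ± 412. The abundant hydrophobin PCI_0227 rose from 4925 ± 1641 to 16585 ± 1725 FPKM, 3.37-fold. Of 52 sugar transport genes 12 rose and 0 fell, while 14 of 54 ribosome biogenesis genes fell and 0 rose.

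Among the other named rises, glucan 1,3-beta-glucosidase A (PCI_0537), which acts on beta-1,3-glucan, rose 8.15-fold (log2 3.00 ± 0.21) and bli-3 (PCI_8271) rose 8.02-fold (2.93 ± 0.23). In 6 further genes the TL2D replicates lay far apart. The MARVEL domain gene PCI_5235 had 128 and 32.8 FPKM in TL2D and 651 ± 79.7 in TL3D, catechol O-methyltransferase 2 (PCI_1264) had 29.2 and 6.85 against 147 ± 17.4, and mfsC (PCI_4943), a multidrug transporter, had 19.8 and 5.15 against 107 ± 7.28. The peptide synthetase anaPS (PCI_8005) had 13.5 and 3.30 against 73.7 ± 0.352, xanE (PCI_8006) had 23.5 and 5.12 against 109 ± 9.62, and the transporter oryC (PCI_7313) had 19.0 and 5.62 against 92.0 ± 11.9. The falls were smaller. An indoleamine 2,3-dioxygenase gene (PCI_3950), for tryptophan breakdown, fell 5.45-fold (log2 −2.35 ± 0.16), an HLH gene (PCI_0608) 3.24-fold, the membrane protein PTH11 (PCI_5819) 3.20-fold, and the peroxidase stcC (PCI_2009) 3.02-fold. The serine-rich protein gene PCI_2348 fell 2.94-fold, the hydrophobin PCI_2115 fell 2.91-fold, the dye-decolorizing peroxidase PCI_6350 fell 2.89-fold and its neighbour in number, galactose oxidase PCI_6351, fell 2.81-fold. The P450 genes adrA (PCI_7156) and pkfB (PCI_5820) fell 2.53-fold and 2.43-fold. Adjusted p over these 20 genes ran from 0.0112 to 0.0497, and with a pseudocount of 0.1 the genes PCI_5235, PCI_1264, PCI_8005 and PCI_8006 lost their call.

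In all, 828 of 8222 tested genes passed (10.1%), 557 higher and 271 lower at day 3, and 423 and 67 of them changed at least 2-fold. Unadjusted, 2496 genes had p under 0.05, and the lowest adjusted p was 0.0112. The values of the groups did not overlap in 63.4% of tested genes, against 33.3% by chance. The authors' own table marks 755 genes, 628 higher and 127 lower, and these include 478 of the 490 genes that changed at least 2-fold here.

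Of 52 sugar transport genes 12 rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000181, adjusted p = 0.97 with an estimated correlation). The hexose transporter HXT10 (PCI_5998) had 8.40 and 0.692 FPKM in the TL2D replicates and 65.2 ± 21 in TL3D (adjusted p = 0.0765 with a pseudocount of 0.1 and 0.0587 with no filter on low values). Of 54 ribosome biogenesis genes 0 rose and 14 fell (0 and 50 adjusted over the list alone), with a median of −0.51 (camera adjusted p = 4.81e-16, adjusted p = 0.97 with an estimated correlation). The U3-associated protein gene PCI_5003 fell 1.70-fold, from 24.1 ± 1.70 to 14.2 ± 2.01 FPKM. Of 73 cytosolic ribosomal protein genes 0 rose and 1 fell (0 and 0 adjusted over the list alone), and at an unadjusted p under 0.05 limma gave 1 up and 24 down. The list median was −0.26 (camera adjusted p = 4.89e-10, adjusted p = 0.97 with an estimated correlation). The gene that fell, PCI_2952, encodes the export factor NMD3, from 102 ± 7.56 to 71.7 ± 2.54 FPKM (adjusted p = 0.0498, but 0.0545 after upper-quartile and 0.0669 after median log ratio scaling). Of 46 amino acid biosynthesis genes 0 rose and 3 fell (0 and 1 adjusted over the list alone), with a median of −0.27 (camera adjusted p = 0.000448, adjusted p = 0.97 with an estimated correlation). Cystathionine gamma-synthase (PCI_8783), of methionine synthesis, fell 1.99-fold.

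Of 32 TCA cycle genes limma called 0 (0 adjusted over the list alone; 1 up and 10 down at an unadjusted p under 0.05, and 1 up and 6 down by the authors' FDR), and the list median was −0.19 (camera adjusted p = 0.00408, adjusted p = 0.97 with an estimated correlation). Without TL2D replicate 2 camera gave an adjusted p of 0.215 for that list. Of 234 transcription factor genes 9 rose and 3 fell (1 and 0 adjusted over the list alone, 16 and 2 after median log ratio scaling), with a median of 0.14 (camera adjusted p = 0.0375, adjusted p = 0.97 with an estimated correlation). Camera's adjusted p for transcription factors was 0.2 without TL2D replicate 1, 0.412 without TL2D replicate 2, 0.102 without TL3D replicate 2 and 0.0578 with the replicate number as a block. The zinc finger gene PCI_5996 fell 1.92-fold. Of 58 respiratory chain genes limma called 0 (0 adjusted over the list alone; 0 up and 1 down at an unadjusted p under 0.05, as by the authors' FDR), and of 21 nicotine and pyridine genes likewise 0 (0 adjusted over the list alone; 0 up and 2 down unadjusted, and 0 up and 1 down by the authors' FDR).

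In the nitrate list 2 of 5 rose and 2 fell, the same adjusted over the list alone. The 2 that had fallen on leaves at day 2 rose, the nitrate reductase PCI_1262 from 4.04 ± 2.5 to 20.5 ± 3.00 FPKM and the copper-containing nitrite reductase PCI_1263 from 0.581 ± 0.771 to 10.4 ± 2.27 (adjusted p = 0.068 with a pseudocount of 0.1 and 0.0647 by the authors' FDR). The nitrite reductase PCI_3792 fell 1.65-fold and the nitrate reductase PCI_3793 fell 1.56-fold, while the nitrate transporter PCI_3791 stood at 52.2 ± 30.9 and 33.7 ± 1.84 (adjusted p = 0.479). The log2 change of PCI_3791 was 0.14 (adjusted p = 0.442) without TL2D replicate 1 and −1.12 (adjusted p = 1.93e-06) without TL2D replicate 2. In conidiation and conidia 4 of 13 rose and 2 fell (5 and 2 adjusted over the list alone), with the hydrophobins PCI_2310, from 1176 ± 536 to 4740.0 ± 444, and PCI_8314, from 65.5 ± 41.6 to 382 ± 2.80, both up. In the citrinin list, matched by name and not the whole cluster, 1 of 4 tested genes rose and 0 fell (1 and 1 adjusted over the list alone), too few for camera's test here. The transporter ctnC (PCI_5755) rose from 3.48 and 0.701 FPKM in the TL2D replicates to 14.4 ± 0.456 (adjusted p = 0.0702 with a pseudocount of 0.1), mrl3 (PCI_3403) stood at 14.8 ± 3.00 and 14.6 ± 0.405 (adjusted p = 0.982), ctnR (PCI_5674) at 1.44 ± 0.117 and 1.91 ± 0.347 (adjusted p = 0.391), and mrr1 (PCI_4327) at 62.5 ± 12.4 and 39.0 ± 0.302 (adjusted p = 0.0693).

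**Figure D3:**
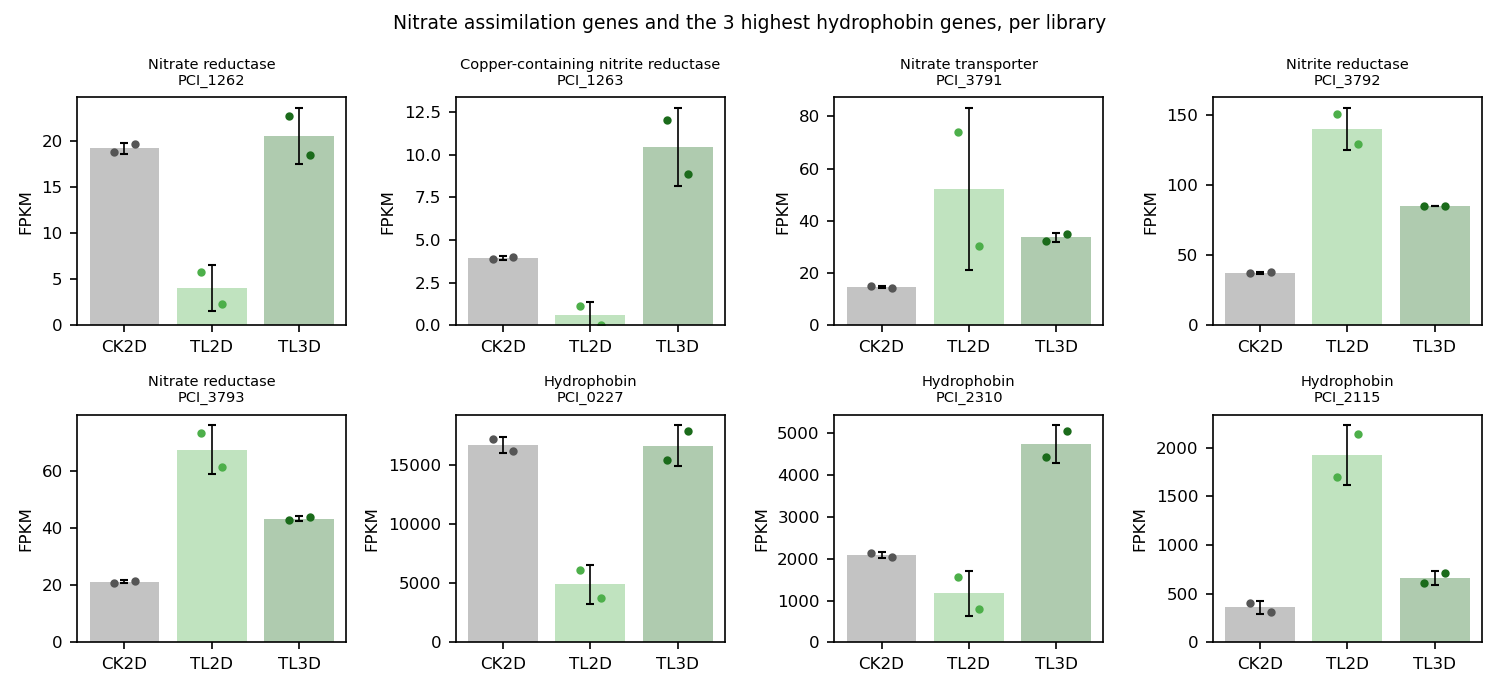
FPKM of the 5 nitrate genes and the 3 hydrophobin genes with the highest mean expression in CK2D, TL2D and TL3D, bars showing the mean, error bars the SD (n = 2) and points the libraries. Hydrophobin PCI_0227 had means of 16661, 4925 and 16585, and PCI_2115 had 359, 1919 and 660.

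The other lists did not pass camera's test, with adjusted p from 0.341 to 0.93. In pectin degradation 2 of 19 rose and 0 fell (2 and 3 adjusted over the list alone), with polygalacturonase 1 (PCI_6785) up 2.99-fold. In cellulose and beta-glucans 3 of 36 rose and 3 fell, the same adjusted over the list alone, with endoglucanase-4 (PCI_1520) down 3.42-fold. In hemicellulose 3 of 42 rose and 3 fell (6 and 3 adjusted over the list alone), with an arabinosidase (PCI_8726) up 2.79-fold and acetylxylan esterase 2 (PCI_4750) down 2.30-fold. In starch and sucrose 1 of 11 rose and 1 fell, the same adjusted over the list alone, alpha-glucosidase PCI_8883 up 1.56-fold and alpha-amylase A (PCI_9413) down 1.59-fold. In cutin and lipids 9 of 59 rose and 1 fell (10 and 3 adjusted over the list alone), with an esterase (PCI_4631) up 4.40-fold and a secreted lipase (PCI_4542) down 1.59-fold. In phenolic oxidases 8 of 31 rose and 3 fell (10 and 5 adjusted over the list alone), and a phenol hydroxylase (PCI_6600) fell 1.89-fold. Without TL2D replicate 1 the phenolic oxidase list passed camera's test (adjusted p = 0.0215).

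In oxidative stress defence 2 of 37 rose and 4 fell (8 and 6 adjusted over the list alone), and the superoxide dismutase PCI_1659 fell again, 6.99-fold (4.46-fold without TL2D replicate 2). In heat shock proteins 3 of 52 rose and 0 fell (5 and 5 adjusted over the list alone), with a 30 kDa heat shock gene (PCI_1906) up 4.99-fold (7.56-fold without TL2D replicate 1). In multidrug transport 10 of 84 rose and 3 fell (11 and 8 adjusted over the list alone), and ABC transporter B (PCI_4946) fell 2.41-fold. In cytochrome P450 0 of 53 rose and 3 fell, the same adjusted over the list alone, with alnD (PCI_7307) down 3.33-fold. In secondary metabolite synthases 3 of 26 rose and 3 fell (7 and 4 adjusted over the list alone), with FUB8 (PCI_8142) down 4.38-fold. In peptidases 7 of 113 rose and 2 fell, the same adjusted over the list alone, with aspergillopepsin-2 (PCI_4066) up 5.98-fold and opsB (PCI_0547) down 2.35-fold. In amino acid transport 1 of 49 rose and 1 fell (0 and 0 adjusted over the list alone), the vacuolar YPQ1 (PCI_7844) up 1.93-fold and a dicarboxylic permease (PCI_6059) down 2.43-fold. In detoxification 2 of 38 rose and 0 fell, the same adjusted over the list alone, with the transferase OpS6 (PCI_6542) up 6.92-fold. In iron and siderophores 2 of 33 rose and 2 fell, the same adjusted over the list alone, with the reductase PCI_5211 up 5.62-fold and another (PCI_9121) down 2.79-fold.

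In cell cycle and DNA replication 11 of 89 rose and 0 fell (13 and 0 adjusted over the list alone), with the DNA repair polymerase pol4 (PCI_4609) up 3.73-fold. In fungal cell wall genes 4 of 36 rose and 5 fell (7 and 8 adjusted over the list alone), PCI_7507 up 9.12-fold and PCI_0926 down 1.79-fold. In effector-type genes 2 of 10 rose and 0 fell (3 and 0 adjusted over the list alone), with the CFEM gene PCI_4577 up 2.98-fold. In proteasome and autophagy 3 of 142 rose and 0 fell (1 and 0 adjusted over the list alone), with the ligase UPL4 (PCI_9089) up 7.58-fold. In glycolysis 1 of 21 rose and 2 fell, the same adjusted over the list alone, with hexokinase-1 (PCI_6407) up 2.25-fold and a phosphoglycerate mutase family gene (PCI_8427) down 1.52-fold. In fatty acid oxidation 3 of 66 rose and 1 fell (2 and 0 adjusted over the list alone), malate synthase (PCI_7166) up 2.48-fold and a thiolase (PCI_1000) down 1.45-fold. Of 6 plant-type names 1 rose and 1 fell, the same adjusted over the list alone, PCI_7450 up 7.38-fold (15.3-fold without TL2D replicate 1) and PCI_9155 down 2.04-fold. The calls between days of PCI_8883, PCI_0547, PCI_7844, PCI_6059, PCI_2952, PCI_5003, PCI_1000, PCI_0926, PCI_9155 and PCI_3793 were each lost under at least 1 of the replicate block, the pseudocount of 0.1, no filter and the scalings, at an adjusted p of 0.0502 to 0.0776. Median, mean and camera's direction differed in sign for cellulose (−0.21, 0.01, down), hemicellulose (0.04, 0.05, down), peptidases (−0.06, 0.06, down), nitrate (−0.49, 0.66, down) and multidrug transport (−0.13, 0.08, down). They also differed for oxidative stress (−0.12, 0.41, down), heat shock (−0.17, 0.00, down), cell cycle (−0.03, 0.07, up), cell wall (−0.19, 0.08, down) and iron (0.02, 0.03, down).

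Limma called 0 genes without TL3D replicate 1 (1074 at an unadjusted p under 0.05) and 0 without TL3D replicate 2 (1198), when the spread comes from the TL2D pair alone, yet all 828 genes kept their direction, with median absolute log2 changes of 1.11 and 1.20 against 1.15 (the authors' deposited FDR marks 1908 genes). Without TL2D replicate 1 or 2 the counts were 3251 and 2054, each holding all 828 genes in the same direction, and leaving out 1 library moved the fold more than 1.5 times in 16 of the 70 named genes, at most 16.2 times (PCI_1263).

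Setting the changes side by side asks whether genes that differ between leaf and plate go on changing on the leaf. Of 8108 genes tested in both comparisons, 426 fell on leaves at day 2 and rose by day 3, among them the hydrophobin PCI_0227, the hexose transporter PCI_5998, aspergillopepsin-2 (PCI_4066) and the ferric reductase component PCI_5211. Another 195 rose and then fell, such as the hydrophobin PCI_2115, methionine synthase PCI_5779 and the nitrite reductase PCI_3792. Few went on in the same direction, 10 rising in both comparisons and 29 falling in both, such as the superoxide dismutase PCI_1659. Independent lists of these sizes would share 149, 68.7, 133 and 76.9 genes in these 4 classes.

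**Figure D4:**
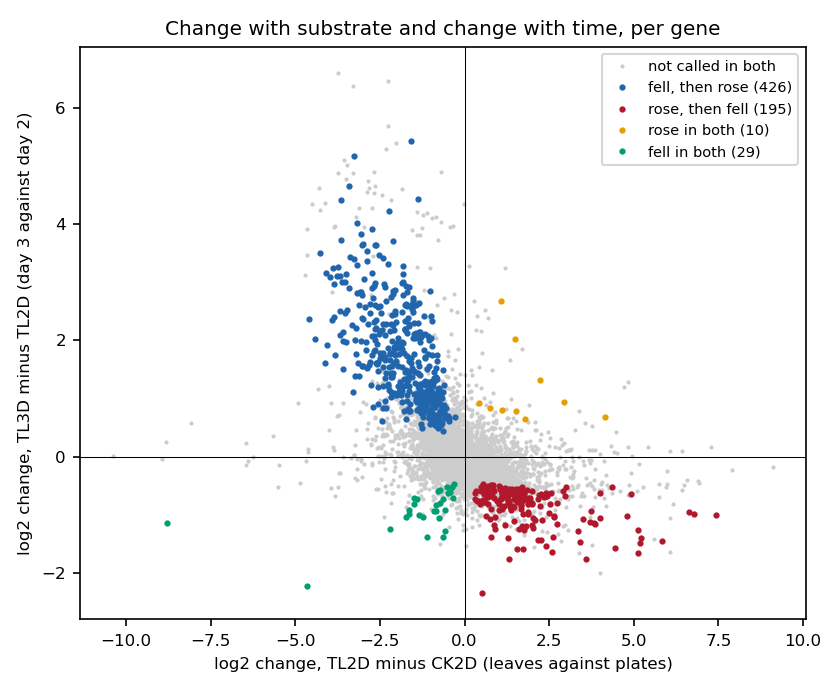
Log2 change from day 2 to day 3 on leaves (TL3D minus TL2D) against the log2 change from plates to leaves at day 2 (TL2D minus CK2D), each point a gene tested in both, with genes called in both coloured by class. The classes hold 426 genes down then up, 195 up then down, 10 up in both and 29 down in both.

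The TL2D libraries enter both comparisons with opposite signs, so part of this excess can come from their chance deviations. The covariance of the 2 changes across genes was −0.441, against −0.0566 on average (lowest −0.0668) in simulated data where the shared libraries alone link them, and −0.369 and −0.406 with a different TL2D replicate in each comparison. Adjusted p is never under 0.01 in the day 3 comparison, so the count of 426 is 0 at that limit in limma, where 2496 genes have an unadjusted p under 0.05.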

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

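In this part, the comparison of TL3D with CK2D was the only test chosen after the result was seen. Leaving out a library leaves a group with a single one, which is then assumed to vary like the other group. For TL2D against CK2D this gave 1131 to 5229 changed genes, 593 to 2230 higher and 510 to 2999 lower, and for TL3D against TL2D 0 to 3251, 0 to 1811 and 0 to 1440. The spread in those fits comes from the group that keeps 2 libraries, so it too changes with the library left out. Of 8407 genes, 360 lay at least 2-fold apart between the TL2D replicates, against 18 in CK2D and 10 in TL3D. List counts ran from 9 to 11 and from 4 to 6, and for TL3D against CK2D 3673 to 4324 genes changed. With a log2 limit of 1 the counts were 1844, 832 and 1012 for leaves against plates, and 490 changed and 67 lower between days, a smaller set by construction. One fit over all 6 libraries gave 1515 changed genes (879 higher, 636 lower) between days, and the authors' FDR gave 1908 (1088 and 820); the cause was not tested. Camera with an estimated correlation called 0 lists in both comparisons (0 at an unadjusted p under 0.05), and fry called 0 between days (3 unadjusted). That form of camera works on only the 2 residual degrees of freedom. The amino acid biosynthesis list had an estimated correlation of 0.01 in both comparisons, the same as the preset. Its camera adjusted p still went from 0.0101 to 0.846 and from 0.000448 to 0.97. The lost calls of that list therefore do not show an effect of correlation among its genes. Some other called lists had higher estimated correlations, with 0.71 and 0.82 for cytosolic ribosomal proteins and 0.51 and 0.45 for ribosome biogenesis. For these, the preset of 0.01 can make camera's p-values too small. There fry gave adjusted p = 0.0407 and 0.301 for ribosomal proteins, and 0.022 and 0.301 for ribosome biogenesis. For leaves against plates fry called 11, of which 7 were among camera's 11. It left out the respiratory chain, iron, proteasome and transcription factor lists (adjusted p = 0.0519, 0.0593, 0.0692 and 0.0801) and added cellulose, multidrug transport, citrinin and plant-type names (0.022, 0.0453, 0.0105 and 0.0348). The count of genes that fell and then rose was 0 at an adjusted p of 0.01, 1026 with TL2D replicate 1 against plates and replicate 2 against day 3, and 797 with the 2 exchanged; the cause was not tested.

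The replicate number as a block gave 3568 and 739 changed genes, and transcription factors lost camera's call in both comparisons (adjusted p = 0.0584 and 0.0578). Replicate differences of different groups correlated across genes at −0.08, −0.25 and 0.17. With 1 difference per group, these values cannot decide whether the replicate numbers pair the libraries. Under the pseudocount, filter and scaling alternatives the counts ran from 4429 to 4502 and from 657 to 863. For leaves against plates lower genes were in the majority (2439 against 2054), but after median log ratio scaling 2327 were higher and 2153 lower. That scaling moved the median log2 change over all tested genes from −0.099 to −0.006, which shifts calls towards higher. By the authors' FDR 2625 were higher and 2385 lower, and the cause of that was not tested. Of the 70 genes named between days, 14 lost their call with a pseudocount of 0.1, 10 with no filter on low values, 8 with the replicate block, 3 after median log ratio scaling and 1 after upper-quartile scaling, and PCI_2952 is among them each time. PCI_1263 lost its call between days by the authors' FDR as well (adjusted p = 0.0647). Of the 90 named for leaves against plates, PCI_3553 and PCI_1263 lost theirs with a pseudocount of 0.1 and by the authors' FDR, PCI_3553 with no filter and PCI_0231 after median log ratio scaling. That scaling also moved small list counts between days, with heat shock rises going from 3 to 5, amino acid transport rises from 1 to 3 and amino acid biosynthesis falls from 3 to 1. For leaves against plates, proteasome and autophagy falls went from 50 to 34 and transcription factor falls from 90 to 80. Fatty acid oxidation falls went from 22 to 15 and heat shock falls from 13 to 9. Shared calls kept their direction under every alternative. A few genes that had not passed the test reversed, and the cause was not tested. PCI_5674 was at 0.0034 on the log2 scale for leaves against plates after median log ratio scaling, and PCI_5755 at 0.49 without TL2D replicate 2 and −0.91 without TL2D replicate 1. Between days PCI_3791 was at 0.14 without TL2D replicate 1 and −1.12 without TL2D replicate 2. PCI_3403 was at 0.19 without TL2D replicate 1, −0.20 without TL2D replicate 2, 0.019 without TL3D replicate 1, 0.0032 after upper-quartile scaling and 0.0025 after median log ratio scaling. DESeq2 and a count filter were not run, since the files hold FPKM. Read depth is unknown, so its limits could not be set.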

Other observations

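The tests chosen after the result was seen were the comparison of TL3D with CK2D and its split by CK2D replicate, the search for list members among genes that fell and then rose, the conidiation test, the replicate 1 axis and the runs of neighbouring numbers. After 3 days on leaves, 4873 of 8356 genes differed from plates at day 2 (2352 higher, 2521 lower). Plates were sampled at day 2 only, so this comparison and its lists cannot tell substrate from age. Of the 832 genes at least 2-fold higher on leaves at day 2, 819 were tested here. Of these, 516 (63%) were still at least 2-fold higher in TL3D than on the day 2 plates. Of the 1012 lower ones, all tested, 456 (45.1%) were still at least 2-fold lower. Both comparisons use the same CK2D libraries, so deviations of CK2D add to these shares. With a different CK2D replicate in each comparison, and the 2-fold limit alone, 56.4% and 64.8% of higher genes and 42.7% and 40.7% of lower ones stayed past it at day 3, against 7.8% and 9.2%, and 7.8% and 6.9%, of all 8255 genes tested in both. In pectin degradation 12 of 20 genes were higher than on plates and 1 lower (median 1.34, camera adjusted p = 0.00056, adjusted p = 0.552 with an estimated correlation). Of the 5 nitrate genes 4 were higher than on plates and 0 lower (median 1.15, camera adjusted p = 0.0177, adjusted p = 0.552 with an estimated correlation). Among the 426 genes that fell and then rose, sugar transport was over-represented with 10 of 50 tested members (odds ratio 4.59, two-sided Fisher's exact test, adjusted p = 0.00712 over 32 lists). That test takes genes as independent, while the estimated correlation within this list was 0.17 and 0.25 in the 2 comparisons. Camera called the list in neither with that correlation, on 2 residual degrees of freedom that let hardly any list pass. Another 3 genes, with names from pigment synthesis, were picked after their values were seen. The laccase abr2 (PCI_7911) went from 240 FPKM on plates to 20.3 ± 11 and then 77.6 ± 6.81 on leaves, and abr1 (PCI_7946) from 341 to 57.3 ± 27.6 and 223 ± 54.1. The polyketide synthase albA (PCI_7912) went from 403 to 18.8 ± 17.7 and 132 ± 2.13, its last change not past the test (adjusted p = 0.0597).

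Genes with consecutive numbers changed together on leaves at day 2. Runs of at least 5 called genes at least 2-fold changed the same way held 75 genes in 10 runs (9 lower, 1 higher, the longest of 16 genes), against at most 11 genes in 1000 random gene orders, which argues against chance neighbours if numbers follow genome order. The citrinin run PCI_3398 to PCI_3407 (median log2 −7.14) and the sorbicillinoid run PCI_3051 to PCI_3057 (−6.44) had medians of −0.01 and 0.01 from day 2 to day 3. Some of their members were near the floor in TL2D, such as PCI_3406 at 0.0667 and PCI_3051 at 0.53 FPKM, and were not tested between days. There log2(FPKM + 1) hides change, so these medians cannot show that the runs stayed level. The run PCI_8003 to PCI_8010 around the peptide synthetase anaPS (−3.49) had 7 of 8 genes rising by day 3 (median 2.67). In PCI_1262 to PCI_1266, with a nitrate reductase and a copper-containing nitrite reductase, all 5 rose (2.93). However, PCI_8005, PCI_8006, PCI_1263 and PCI_1264 lost that call with a pseudocount of 0.1. Shared control of neighbouring genes may explain such runs, and it was not tested here.

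TL2D replicates 1 and 2 lay at least 2-fold apart in 360 genes, against 18 and 10 in the other groups. The tables argue against a difference in scale, since 330 genes stayed apart after median log ratio scaling, above a limit of 34 set at double the larger other group. RNA of a day 3 culture mixed into replicate 1 would give 1 mixing share for all genes, apart from noise. Over 210 genes the quartiles of the implied share differed 2.44-fold (95% bootstrap interval 2.03 to 3.28), around a median of 12.3%. In the same genes the quartiles of TL3D replicate 1 over replicate 2 differed 1.48-fold. The interval resamples genes and does not measure noise between libraries, so the spread of shares cannot decide on mixing. However, 104 of the 360 genes were lower in replicate 1, and a share near that median would not make a gene 2-fold lower. Replicate 1 may instead have lain further along the change from day 2 to day 3, but this stays open. Its difference from replicate 2 correlated across genes at 0.54 with TL3D minus the TL2D mean, which noise in replicate 2 also raises. With TL3D minus replicate 1 it correlated at 0.24 (Spearman 0.06), where noise in replicate 2 gives 0 and noise in replicate 1 lowers the value. Replicate 1 correlated with the TL3D libraries at 0.964 and 0.97, and replicate 2 at 0.935 and 0.944. With the CK2D libraries the values were 0.886 and 0.886 against 0.868 and 0.867. In the 360 genes replicate 1 was on the TL3D side of replicate 2 in 328 and on the CK2D side in 273. Noise in replicate 2 raises both counts. Replicate 1 lay between replicate 2 and the TL3D mean in 187 of the 360, a count that noise in replicate 2 alone does not raise. A deviation of replicate 2 was not tested and stays open too. In 30 genes at least 20-fold higher on plates than in TL3D, the implied plate share of replicate 1 was at most 1.0% (median 0.0445%).

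The 426 genes that fell on leaves at day 2 and rose by day 3 are the third pattern. Chance deviations of the shared TL2D libraries would give no covariance with a different TL2D replicate in each comparison. The covariance nearer 0 was −0.3691, below the lowest simulated value of −0.0668. It was taken over all 8108 genes tested in both comparisons. It argues against chance for the opposite changes as a whole, but cannot tell how many of the 426 genes owe their calls to it. A few abundant genes taking more of the FPKM total would be removed by scaling, and 96% of these genes (409 of 426) kept both calls after it. Lower conidiation at day 2 on leaves could be a cause, but 2 of 13 conidiation genes in the set (odds ratio 3.29, two-sided Fisher's exact test p = 0.147) are too few to decide. A deviation common to both TL2D libraries was not tested and stays open.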
